A study of Homo sapiens with 8 samples.

How the data were processed

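Gene expression in 293T cells with a control hairpin (NCsh) or a hairpin against H1.2, Cul4A or PAF1 was measured on 8 arrays, 2 in each of 4 groups. Total RNA was isolated with TRIzol, and biotinylated cRNA was made with an Ambion MessageAmp kit for Illumina arrays, per the labels' protocols. The software and settings behind the values are not given in the sources used here.

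The authors' deposited scanner table holds a bead signal (a linear intensity) and a detection p-value for each of 47220 probes. No normalization of its signal columns between arrays was seen in the values. It has 16 columns of values, of which 2 are empty and were not used, so 7 arrays have values. A second deposited table, the authors' series matrix, holds a linear intensity per probe for all 8 arrays. The scanner table could be set against 7 of the matrix columns, over probes with a signal above 400. Each of these columns was the signal of 1 array minus an amount that differed between probes in whole-number steps (within 0.01 for 100% of these probes, SD of the amount 4.91 to 5.12). The matrix is therefore background-adjusted, linear, not centred and, like the scanner signals, without a normalization between arrays. For the matrix column without a scanner match this was assumed. How the adjustment was made is not known. The array medians of the matrix lay between 82.8 and 88.7, its 75th percentiles between 140 and 162, and its lowest value was 50.2. Background thus stays in the values after the adjustment. Fold changes are likely smaller than they would be without it, most of all for dim probes.

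The names in the 2 tables disagree for 2 arrays. The scanner columns named for H1.2sh replicate 2 and Cul4Ash replicate 2 match the matrix arrays of Cul4Ash replicate 2 and PAF1sh replicate 2, and the matrix array of H1.2sh replicate 2 has no scanner column. The other 5 scanner columns match the matrix array of the same name. Matrix columns are tied to their samples by accession, and groups were taken from the sample labels through the matrix. The plan fixed before the data were examined had been to start from the scanner signals with limma's neqc. Because that table lacks 1 array and has 2 disputed names, the matrix values became the main input, and neqc on the 5 undisputed scanner arrays became an alternative, which made 0 calls for H1.2sh and Cul4Ash against NCsh. The planned filter, detection on both arrays of at least 1 group, needs the group of every scanner array and was replaced by detection on any 2 arrays. The filter used detection p-values without group names, so the disputed names do not affect it. By the match with the matrix, however, only 1 scanner array is of H1.2sh. A gene above background in H1.2sh alone would thus tend to be lost, while a gene below background there alone would be kept. The smallest detection p-value above 0 was 0.00100 on the array of Cul4Ash replicate 1 and 0.00130 on the other scanner arrays.

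Matrix values were log2 transformed and quantile normalized between arrays. A probe was kept if its detection p-value was under 0.05 on at least 2 of the 7 scanner arrays. In the matrix, 64 probes had no value on any array and 2 lacked one on a single array; they were left out, which removed 5 genes entirely. Gene names came from GEO's platform annotation, in which 30109 probes had 1 gene symbol, 8 had several and 17103 had none; 30070 were looked up by Entrez ID in the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. Of 22131 probes kept, 16305 had 1 gene, and for the 3167 genes with more than 1 kept probe the probe with the highest mean over the 8 arrays was used. This gave 12300 genes. No coordinates are given, since the files name no genome build.

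Each gene was fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with 4 group means over all 8 arrays, 4 residual and 6.19 prior degrees of freedom. Tested were each depletion against NCsh and the 3 depletions against each other, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. Of 36 gene lists fixed before the data were examined, the 34 with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01; the linker histone list had 3 measured genes and mitochondrially encoded transcripts had 0. No list passed in any comparison with an estimated correlation, for which 4 residual degrees of freedom are available. At an unadjusted p under 0.05 that test gave 7, 5 and 5 lists for H1.2sh, Cul4Ash and PAF1sh. The other lists were the CUL4 ubiquitin ligase, H2B ubiquitylation and histone H3 methylation, elongation factors, interferon-stimulated genes, NF-kB targets, endoplasmic reticulum chaperones, cytosolic ribosomal proteins, apoptosis, Wnt, Notch and NRF2 genes, and none of these passed against NCsh with quantile normalization, the lowest adjusted p among them being 0.0639 for NRF2 genes in H1.2sh. With median scaling and without normalization, NRF2 genes (adjusted p = 0.0152 under both) and cytosolic ribosomal proteins (adjusted p = 0.0235 under both) passed in H1.2sh. These settings differ only by a constant per array, which moves all genes alike. Camera compares a list with other genes, so its results under both are nearly the same test, here and below.

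Genes were named by a rule fixed before the data were examined: the targets with their other probes, the 6 genes with the largest change per direction in each depletion, up to 4 changed members of each list, up to 8 genes per direction changed in all 3 depletions, up to 3 per direction in each direct comparison, and the genes of the PAF1 complex, the linker histones and CUL4. Where the probe of a called gene had no detection p-value under 0.05 on any scanner array of the dimmer group, only a bound is given. This used the 5 scanner arrays with undisputed names, which are both NCsh arrays and 1 array of each depletion. It sets the brighter group's mean against the dimmer group's mean. The dimmer mean takes, on each array, the higher of the probe's own value and the lowest value of a detected probe. The other array of each depletion entered at its own value. Such a bound allows for no spread between arrays, so the true change may be smaller. Unnamed-type symbols (such as those starting with LOC) were passed over. The rule also takes members of lists with at least 3 changed genes; members of lists that did not pass camera are left out of the text for length. The marker genes of other cell types were named after their values were seen.

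The fit was tested on simulated data with the real means and spreads, 12300 genes and 200 changed genes in each of 10 draws. Noise was drawn independently for each gene from the model that limma assumes. The shares below thus hold under that model only and do not cover correlated genes, spread between cultures or a larger number of changed genes. For H1.2sh against NCsh it recovered 30.7% of genes changed 1.25-fold, 94.8% of those changed 1.5-fold and 99.7% of those changed 2-fold, with 5.43% of calls not planted. For Cul4Ash the shares were 31.8%, 95.8% and 100%, with 6.37% not planted, and for PAF1sh 32.1%, 95.5% and 99.7%, with 5.26% not planted. Unchanged groups were simulated 100 times against the shared controls.

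The planned median scaling after neqc was run on the matrix values, and the planned stricter filter on 7 arrays in place of 8. Alternatives covered the input values, background correction, scaling, the filter, the choice of probes, the prior, array weights, the arrays in the fit, the replicate number as a block, the threshold and each array left out. The BeadChip as a block could not be tried, since the files name no chip. Replicate numbers were not used to pair arrays. Probes without a gene name were tested separately, over all 22131 probes kept.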

Results

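Gene expression was measured in HEK 293T cells, a human embryonic kidney line that carries the SV40 large T antigen, after depletion of 1 of 3 chromatin or transcription proteins by a short hairpin RNA. The hairpins were directed at the linker histone H1.2 (H1.2sh), at Cul4A, the scaffold of a ubiquitin ligase (Cul4Ash), or at PAF1, a subunit of the PAF1 complex that travels with RNA polymerase II (PAF1sh), and cells with a control hairpin (NCsh) served as reference. Total RNA was hybridized to Illumina bead arrays, 8 in all, with 2 arrays for each of the 4 groups. The number of arrays limits the precision. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The median intensity of an array lay between 82.8 and 88.7, and between 39.2% and 42.5% of the probes of an array were detected above background. After normalization, arrays of the same group correlated at 0.996 (Pearson, lowest and highest both at this value), and arrays of different groups at 0.973 to 0.989. These values are over the 12300 genes, each at its brightest kept probe. The comparisons below ask how each depletion changed gene expression and how far the 3 depletions changed it alike. The labels name no second hairpin against any target and no rescue. Effects of losing a target therefore cannot be told apart from other effects of its hairpin. Log2 changes are given with their standard error from limma, at n = 2 arrays per group, and every gene said to rise, fall or differ passed an adjusted p of 0.05 over the 12300 genes tested. Changes given as at least some fold are bounds set by measured means. They allow for no spread between arrays, so the true change may be smaller.

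Each targeted gene was lowest on the arrays whose labels name it. The H1.2 gene, H1-2 (probe ILMN_1757406), had log2 intensities of 8.05 and 8.05 on the H1.2sh arrays and 9.24 and 9.07 on the NCsh arrays, which is a change of -1.11 ± 0.09 (adjusted p = 4.39e-05) or 2.15-fold lower. Its change was 0.12 ± 0.09 in Cul4Ash and 0.01 ± 0.09 in PAF1sh. CUL4A (probe ILMN_1695792) was at 6.91 and 6.88 on the Cul4Ash arrays and at 8.46 and 8.33 on the NCsh arrays, 2.84-fold lower (-1.51 ± 0.08, adjusted p = 6.96e-06). A second CUL4A probe was not above background on the 1 Cul4Ash array with an undisputed detection p-value and changed by -0.34 in H1.2sh, where the first probe changed by 0.01, and another CUL4A probe was not detected on any array. That undetected probe still had matrix values of 66.8 to 84.6. Background thus stays in the values, and the folds given for the targets are likely too small. PAF1 (probe ILMN_1669508) was at 7.92 and 8.03 on the PAF1sh arrays and at 10.61 and 10.50 on the NCsh arrays, 5.99-fold lower (-2.58 ± 0.08, adjusted p = 5.73e-08). PAF1 changed by 0.17 ± 0.08 in H1.2sh and by 0.00 ± 0.08 in Cul4Ash, neither past the threshold. CUL4B, the paralog of CUL4A, did not pass the threshold in any depletion, with changes of -0.31 ± 0.12 in H1.2sh, -0.10 ± 0.12 in Cul4Ash and 0.11 ± 0.12 in PAF1sh.

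**Figure D1:**
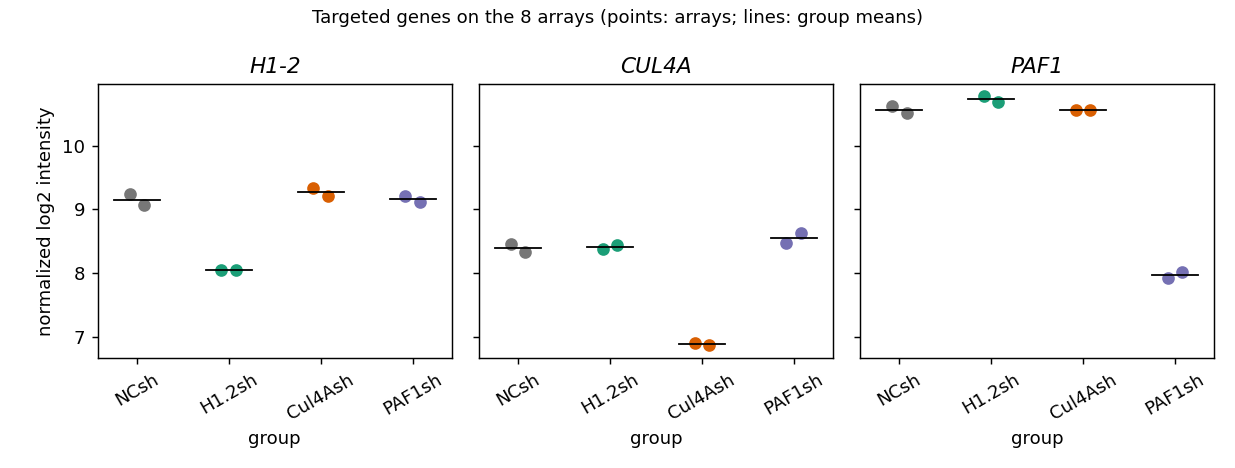
Normalized log2 intensity (vertical axis) of the 3 targeted genes on the 8 arrays, by group (horizontal axis); points are single arrays and lines are means of 2 arrays. H1-2 lies near 8.05 on both H1.2sh arrays, CUL4A near 6.89 on both Cul4Ash arrays and PAF1 near 7.97 on both PAF1sh arrays, each below all other arrays.

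In H1.2sh, the genes that fell most were GLTP, which encodes a glycolipid transfer protein (-1.74 ± 0.08), ACTA2, a smooth muscle actin (-1.61 ± 0.09), the choline transporter gene SLC44A1 (-1.50 ± 0.07), CHCHD6, a gene of the mitochondrial inner membrane (-1.49 ± 0.11), the glycolysis regulator PFKFB4 (-1.44 ± 0.09) and the histone gene H2BC5 (-1.42 ± 0.09). The genes that rose most were EMILIN2, which encodes an extracellular matrix glycoprotein (1.58 ± 0.08), ID3, an inhibitor of helix-loop-helix transcription factors (1.52 ± 0.07), the heme oxygenase gene HMOX1 (1.48 ± 0.09), RHOC (1.35 ± 0.08), BHLHE22 (1.30 ± 0.09, with 1 of the 2 NCsh arrays above background) and SFXN1, a mitochondrial serine transporter gene (1.27 ± 0.13). All of these had adjusted p-values of 0.000159 or less. In all, 895 genes rose and 1003 fell, of which 9 and 58 changed at least 2-fold. The filter on detection had only 1 H1.2sh array to use. Genes above background in H1.2sh alone would tend to be lost, so the counts of genes that rose may be too low.

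Genes of glycolysis and the hypoxia response, cholesterol synthesis and heat shock were lower in H1.2sh. Of 31 measured genes of glycolysis and the hypoxia response, 11 fell, 2 rose and 18 did not pass the test (15 and 2 when adjusted over the list alone). Besides PFKFB4, they included BNIP3 (-1.18 ± 0.09), the glucose transporter gene SLC2A1 (-1.14 ± 0.08) and the prolyl hydroxylase gene P4HA1 (-1.04 ± 0.09). Of 19 cholesterol synthesis genes, 7 fell and 0 rose (9 and 0 when adjusted over the list alone), among them HMGCS1 (-0.84 ± 0.08) and INSIG1 (-0.84 ± 0.08). Of 21 heat shock genes, 5 fell and 0 rose, among them HSPA1B (-0.83 ± 0.07) and DNAJB1 (-0.68 ± 0.09), and adjusted over the list alone the counts were 5 and 0. HSPA1A, at least 2.25-fold lower (adjusted p = 0.000128), was not above background on the 1 H1.2sh array with an undisputed detection p-value. The adjusted camera p was 0.000177 for the glycolysis and hypoxia list, 0.000477 for cholesterol synthesis and 0.00139 for heat shock, and with an estimated correlation the adjusted p was 0.229, 0.210 and 0.210. Of 21 neuronal genes, 5 fell and 0 rose (6 and 0 when adjusted over the list alone), such as INA (-1.14 ± 0.08) and STMN3 (-0.88 ± 0.08). The neuronal list had an adjusted p of 0.0115, and of 0.210 with an estimated correlation.

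Genes of DNA replication were higher in H1.2sh. Of 46 S-phase genes, 8 rose and 0 fell (10 and 0 when adjusted over the list alone), including the replicative helicase subunit MCM5 (0.62 ± 0.09), thymidine kinase TK1 (0.49 ± 0.08) and the primase gene PRIM1 (0.45 ± 0.08); the adjusted camera p was 0.000125, and 0.173 with an estimated correlation. Of 30 ribosome biogenesis genes, 8 rose and 0 fell (10 and 0 when adjusted over the list alone), such as PPAN (0.71 ± 0.08) and RRP9 (0.53 ± 0.08). Their list had an adjusted p of 0.00300 and of 0.210 with an estimated correlation. Of 18 TGF-beta target genes, 8 rose and 1 fell (9 and 2 when adjusted over the list alone), led by ID3, ID1 (0.66 ± 0.10) and SNAI2 (0.61 ± 0.08), with an adjusted p of 0.00221 and of 0.211 with an estimated correlation. TGFBI was at least 1.72-fold higher by its measured means (adjusted p = 0.0137), a bound because its probe was not above background on the NCsh arrays. Of 37 genes of the ATF4 and amino acid response, 8 rose, 4 fell and 25 did not pass (12 and 4 when adjusted over the list alone). Those that rose included the stress transcription factor gene DDIT3 (0.81 ± 0.09) and the methionine tRNA synthetase gene MARS1 (0.64 ± 0.07), while the glycine tRNA synthetase gene GARS1 fell (-0.86 ± 0.08). That list's adjusted p was 0.0115, and 0.259 with an estimated correlation. These 4 lists passed under the other scalings too, which are nearly the same camera test, with smaller means. From quantile normalization to median scaling to no normalization, the mean change went from 0.16 to 0.086 to 0.067 for S-phase genes and from 0.16 to 0.089 to 0.070 for ribosome biogenesis. For TGF-beta targets it went from 0.28 to 0.20 to 0.18, and for the ATF4 list from 0.10 to 0.033 to 0.014.

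A further 6 lists passed the list test in H1.2sh. Proteasome subunit genes (3 of 27 rose, 0 fell, adjusted p = 0.00838) and splicing factor genes (7 of 46 rose, 0 fell, adjusted p = 0.0223) were higher, each with an adjusted p of 0.210 with an estimated correlation. With median scaling and without normalization both passed, but the mean change fell from 0.12 to 0.061 and 0.042 for the proteasome and from 0.085 to 0.024 and 0.0046 for splicing. PAF1 complex genes were higher with quantile normalization (1 of 5 rose, 0 fell, adjusted p = 0.0202, and adjusted p = 0.210 with an estimated correlation) but did not pass with median scaling or without normalization (adjusted p = 0.0680 under both). Their mean change of 0.24 moved to 0.16 with median scaling and 0.14 without normalization. Of 27 genes of Polycomb proteins and DNA methylation enzymes, 5 rose and 1 fell, with an adjusted p of 0.0455 and of 0.388 with an estimated correlation. The Polycomb list did not pass under either other scaling (adjusted p = 0.106 under both), and its mean change of 0.099 moved to 0.016 with median scaling and turned to -0.0033 without normalization. The PAF1 complex gene that rose was SKIC8 (0.42 ± 0.07), while CTR9 (0.19 ± 0.09), LEO1 (0.22 ± 0.10) and RTF1 (0.18 ± 0.08) did not pass. P53 target genes were lower (6 of 24 fell, 2 rose, adjusted p = 0.0386), among them PHLDA3 (-0.78 ± 0.12), PMAIP1 (-0.69 ± 0.08) and CDKN1A (-0.47 ± 0.08), with an adjusted p of 0.210 with an estimated correlation. Their mean was -0.16, and -0.25 and -0.26 under the other scalings. Extracellular matrix and adhesion genes were lower as a list with quantile normalization (8 of 33 fell, 4 rose, adjusted p = 0.0455, and adjusted p = 0.211 with an estimated correlation) but did not pass under either other scaling (adjusted p = 0.106 under both). Their mean was -0.11, and -0.18 with median scaling and -0.20 without normalization, where the median of all genes also moved down, to -0.071 and -0.090. In that list COL4A6 was at -1.33 ± 0.11 and TIMP1 at 0.85 ± 0.08. Adjusted over the list alone, the genes that rose and fell were 2 and 0 for the proteasome, 7 and 0 for splicing, 1 and 0 for the PAF1 complex, 5 and 1 for Polycomb, 2 and 8 for p53 targets and 4 and 11 for the matrix list. Of the linker histone genes measured, only H1-2 fell, and H1-1 (-0.17 ± 0.08) and H1-10 (-0.09 ± 0.08) did not pass. Core histone genes did not pass as a list in H1.2sh, although 6 of 27 fell and 1 rose, also when adjusted over the list alone. Their mean change was -0.10 and their median 0.01, and the adjusted p of limma's camera was 0.483.

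The setting planned before the data were examined, neqc on scanner signals, could be run on 5 arrays only, and there limma called 0 genes higher and 0 lower in H1.2sh, with 2611 at an unadjusted p under 0.05; the matrix values of those arrays gave 340 and 398. With neqc at an offset of 50 the counts were 327 and 414, and with all 8 arrays and no filter on dim probes 465 and 571. The comparison of H1.2sh with NCsh gave fewer calls whenever 1 of its own arrays was left out: 365 higher and 498 lower without NCsh replicate 1, 474 and 601 without NCsh replicate 2, 306 and 446 without H1.2sh replicate 1, and 427 and 480 without H1.2sh replicate 2. The balance of directions depended on the scaling, since 47.2% of the genes called were higher with quantile normalization, 18.1% with median scaling (264 higher and 1198 lower) and 14.2% without normalization between arrays (201 and 1214).

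In Cul4Ash, the genes that fell most were the formin gene DIAPH1 (-2.33 ± 0.08), the mitochondrial adenylate kinase gene AK4 (-2.0 ± 0.08), the glycine transporter gene SLC6A9 (-1.60 ± 0.08), CUL4A itself, the chemokine gene CXCL16 (-1.44 ± 0.08) and WSCD1 (-1.44 ± 0.11). A second SLC6A9 probe was not above background on the NCsh arrays and did not show the decrease. The genes that rose most were SHISA2 (1.46 ± 0.09), the histone genes H2AC19 (1.44 ± 0.08) and H2AC18 (1.40 ± 0.09), EMILIN2 (1.44 ± 0.08), the dystrobrevin gene DTNA (1.32 ± 0.08) and ID3 (1.22 ± 0.07). H2AC18 and H2AC19 are near-identical copies, so their probes may read the same transcripts and their separate values are uncertain. In all, 1358 genes rose and 1180 fell, of which 27 and 73 changed at least 2-fold.

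Core histone genes were higher in Cul4Ash: of 27 measured, 13 rose, 0 fell and 14 did not pass (18 and 0 when adjusted over the list alone). They included H2AC20 (1.2 ± 0.08) and H2AC6 (1.03 ± 0.10) besides the genes named above, and the list's adjusted camera p was 1.3e-07, or an adjusted p of 0.103 with an estimated correlation. Genes of oxidative phosphorylation were also higher, with 21 of 70 up and 0 down (32 and 1 when adjusted over the list alone), such as UQCR10 of complex III (0.88 ± 0.10), ATP5MC1 of the ATP synthase (0.59 ± 0.09) and NDUFA11 of complex I (0.54 ± 0.08). Their adjusted p was 1.3e-07, and 0.118 with an estimated correlation, and their mean of 0.19 fell to 0.11 with median scaling.

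Genes of the ATF4 and amino acid response were lower in Cul4Ash. Of 37 measured, 20 fell and 2 rose (23 and 2 when adjusted over the list alone), including the stress-induced gene DDIT4 (-1.23 ± 0.08), the asparagine synthetase gene ASNS (-1.10 ± 0.08), STC2 (-1.10 ± 0.08) and PCK2 (-1.04 ± 0.09). The adjusted camera p was 7.97e-09, and 0.118 with an estimated correlation. Of 21 heat shock genes, 9 fell and 1 rose (11 and 1 when adjusted over the list alone), among them HSPA6 (-1.17 ± 0.10), HSPA1B (-1.10 ± 0.07) and BAG3 (-0.95 ± 0.07). That list had an adjusted p of 3.21e-05 and of 0.20 with an estimated correlation. The SKIC8 gene of the PAF1 complex rose (0.48 ± 0.07), and LEO1 (-0.16 ± 0.10), CTR9 (0.00 ± 0.09) and RTF1 (0.00 ± 0.08) did not pass. With neqc on 5 arrays limma called 0 genes higher and 0 lower in Cul4Ash, with 3160 at an unadjusted p under 0.05, and the matrix values of those arrays gave 701 and 631. An offset of 50 in neqc gave 723 and 659, and all 8 arrays with no filter on dim probes gave 866 and 715. Leaving out 1 array of the comparison gave 690 higher and 644 lower without NCsh replicate 1, 892 and 765 without NCsh replicate 2, 729 and 599 without Cul4Ash replicate 1, and 828 and 711 without Cul4Ash replicate 2. Of the genes called, 53.5% were higher with quantile normalization, 28.2% with median scaling (503 higher and 1279 lower) and 41.8% without normalization (571 and 794).

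PAF1sh differed from NCsh in more genes than either other depletion did, with 2335 higher and 2447 lower, of which 91 and 160 changed at least 2-fold. After AK4 (-2.72 ± 0.08) and PAF1 itself, the genes that fell most were the neurofilament gene NEFM (-2.12 ± 0.08), LRATD2 (-2.04 ± 0.09), the cyclin D1 gene CCND1 (-1.98 ± 0.08) and the sphingolipid desaturase gene DEGS1 (-1.91 ± 0.08). TRIM51 rose 11.3-fold (3.50 ± 0.10), followed by TRIM49C (at least 3.48-fold, not above background on the NCsh arrays), YPEL3 (1.74 ± 0.09), the collagen VII gene COL7A1 (1.73 ± 0.09), the protocadherin gene PCDH7 (1.70 ± 0.09) and the p53-induced gene TP53INP1 (1.69 ± 0.09). TRIM51 and TRIM49C belong to a gene family with close copies, so which copy the probes read is uncertain.

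Genes of G2 phase and mitosis were higher in PAF1sh: of 51 measured, 28 rose and 3 fell (31 and 3 when adjusted over the list alone), among them the phosphatase gene CDC25C (1.31 ± 0.09), CENPF (1.26 ± 0.08), NEK2 (0.93 ± 0.09) and KIF2C (0.74 ± 0.08). The adjusted camera p was 1.64e-06, and 0.237 with an estimated correlation. Core histone genes were higher too, with 15 of 27 up and 1 down (16 and 1 when adjusted over the list alone), led by H2AC19 (1.15 ± 0.08), H2AC18 (1.08 ± 0.09) and H2AC20 (1.02 ± 0.08). The histone list had an adjusted p of 3.52e-05 and of 0.154 with an estimated correlation. Of 27 lysosome and autophagy genes, 15 rose and 2 fell (17 and 2 when adjusted over the list alone), such as the neuraminidase gene NEU1 (0.93 ± 0.09), the cathepsin genes CTSA (0.85 ± 0.08) and CTSD (0.65 ± 0.11), and the autophagy kinase gene ULK1 (0.71 ± 0.09). Their adjusted p was 0.000211, and 0.154 with an estimated correlation. Of 24 immediate early genes, 14 rose and 2 fell, as when adjusted over the list alone (adjusted p = 0.000607, and 0.260 with an estimated correlation), including DUSP1 (1.62 ± 0.08), SGK1 (1.13 ± 0.08) and ATF3 (1.10 ± 0.08), while MYC, also on the list, fell (-1.18 ± 0.07).

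The lists below were lower in PAF1sh. Of 31 glycolysis and hypoxia genes, 15 fell and 1 rose, with the same counts when adjusted over the list alone, including SLC2A1 (-1.51 ± 0.08), PFKFB3 (-1.27 ± 0.08) and PFKP (-1.07 ± 0.08). This list had an adjusted p of 0.000124 and of 0.277 with an estimated correlation. Of 21 heat shock genes, 13 fell and 3 rose, such as HSPA4 (-1.11 ± 0.11) and HSPA6 (-1.03 ± 0.10), with an adjusted p of 0.0147 and of 0.277 with an estimated correlation. Of 25 HOX genes, 11 fell and 4 rose, including HOXB13 (-1.43 ± 0.11), HOXD9 (-1.21 ± 0.13), HOXB5 (-1.18 ± 0.08) and HOXB9 (-1.15 ± 0.09), and of 21 neuronal genes, 8 fell and 2 rose, including STMN3 (-1.57 ± 0.08) and UCHL1 (-0.89 ± 0.10). Both of these lists had an adjusted p of 0.0391, and of 0.260 with an estimated correlation. For the heat shock, HOX and neuronal lists the counts adjusted over the list alone were the same as over all genes. P53 target genes did not pass as a list (9 of 24 rose and 3 fell, or 11 and 3 when adjusted over the list alone, adjusted p = 0.0550), but passed as higher with median scaling and without normalization (adjusted p = 0.00890 under both). The linker histone gene H1-10 rose (0.87 ± 0.08), and the other PAF1 complex genes did not pass, with CTR9 at 0.25 ± 0.09, SKIC8 at 0.19 ± 0.07, RTF1 at 0.08 ± 0.08 and LEO1 at -0.01 ± 0.10. With neqc on 5 arrays 807 genes were higher and 1210 lower. No array left out moved either count of this comparison by over 1.5 times, and 1482 genes were higher and 2248 lower with median scaling and 1413 and 2069 without normalization.

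**Figure D2:**
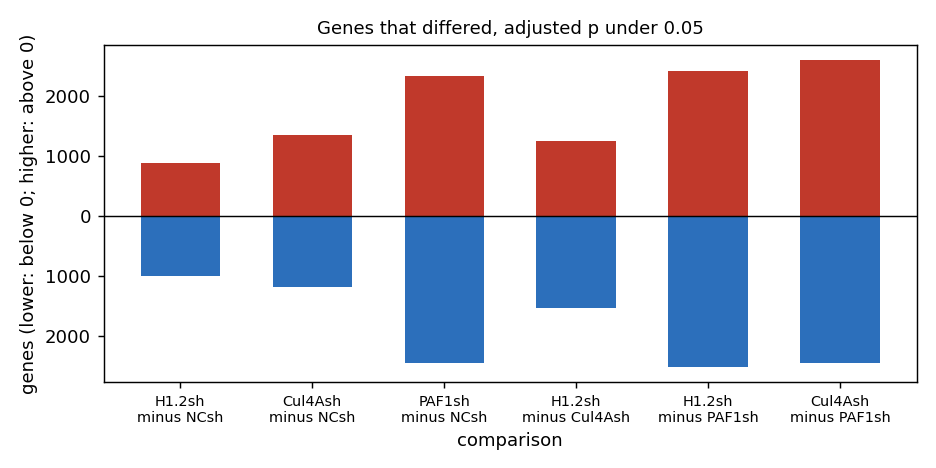
Number of genes (vertical axis) that were higher (above 0) or lower (below 0) at an adjusted p under 0.05 in each of 6 comparisons (horizontal axis; the first-named group relative to the second), from 2 arrays per group. The bars for the comparisons with PAF1sh are longest, with 2335 higher and 2447 lower against NCsh.

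**Figure D3:**
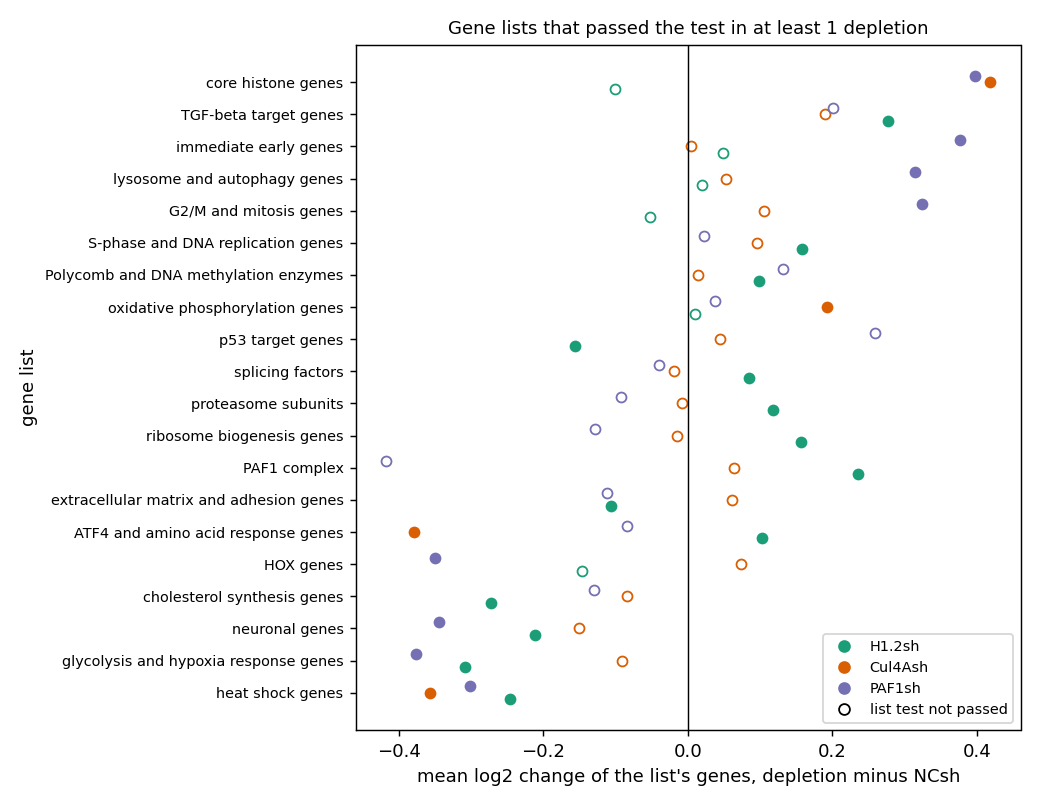
Mean log2 change of the genes of each list (horizontal axis) in the 3 depletions, for the lists (vertical axis) that passed the camera test in at least 1 of them; filled points passed. Core histone genes lie at 0.42 in Cul4Ash and 0.40 in PAF1sh and at -0.10 in H1.2sh.

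Marker lists of other cell types did not pass camera in any depletion, the lowest adjusted p being 0.378 for blood cell markers in Cul4Ash. In limma's fry, which tests a list against no change and not against other genes, blood cell markers passed as lower in Cul4Ash (adjusted p = 0.0209) and PAF1sh (adjusted p = 0.0371), and no other marker list passed. Of 12 blood cell markers, 0 rose and 1 fell in H1.2sh, 0 and 2 in Cul4Ash and 1 and 3 in PAF1sh (0 and 1, 0 and 2, and 0 and 3 when adjusted over the list alone). The hemoglobin gene HBA2, at its brighter probe, was at -0.48 ± 0.07 in H1.2sh, -1.19 ± 0.07 in Cul4Ash and -1.06 ± 0.07 in PAF1sh, and fell in each. CORO1A was at least 1.29-fold lower in Cul4Ash (adjusted p = 0.0133) and fell in PAF1sh (-0.29 ± 0.08). In PAF1sh the hemoglobin gene HBA1 was at least 1.44-fold lower (adjusted p = 0.0213). Neither bounded gene was above background on the 1 array of that depletion with an undisputed detection p-value. LCP1 rose in PAF1sh (0.30 ± 0.11). HBB did not pass in any depletion. Of 7 epithelial markers, SPINT2 fell in Cul4Ash (-1.30 ± 0.10) and PAF1sh (-0.57 ± 0.10). Of 5 fibroblast markers, FBLN1 fell in H1.2sh (-0.39 ± 0.09) and rose in Cul4Ash (0.48 ± 0.09), and TAGLN rose in PAF1sh (0.69 ± 0.09).

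Some genes moved the same way in all 3 depletions. Of the 196 genes higher in each, those with the largest changes by the smallest of their 3 values were RHOC (1.35 ± 0.08 in H1.2sh, 1.09 ± 0.08 in Cul4Ash and 1.58 ± 0.08 in PAF1sh), PCDH7, ID3, NUP160, VGLL4, GMPPB, NDRG4 and PRSS23. Of the 202 genes lower in each, they were the glucose transporter gene SLC2A1 (-1.14 ± 0.08, -0.99 ± 0.08 and -1.51 ± 0.08), PFKFB4, MGAT3, ADAP1, the carbonic anhydrase gene CA2, PPP2R2C (not above background on the 1 PAF1sh array with an undisputed detection p-value), CAMKV and IGDCC3. HSPA6 and HSPA1B, 2 heat shock genes, also fell in each. Across the 12300 genes, which are not independent replicates, log2 changes correlated at 0.413 (Pearson; Spearman 0.415) between H1.2sh and Cul4Ash, at 0.293 (0.273) between H1.2sh and PAF1sh and at 0.304 (0.289) between Cul4Ash and PAF1sh.

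These comparisons share their control arrays. Independent lists of the same lengths would share 18.8 genes upwards and 19.1 downwards. Simulated groups without any change, cut to lists of the same lengths, shared 247 and 244 on average through the controls alone, more than the 196 and 202 observed. Those simulated lists hold noise only and were forced to these lengths. The counts therefore show how strongly shared controls can act, and cannot decide how many of the observed shared genes come from them. At the threshold itself such groups gave 0.53 calls on average over the 3 comparisons. Opposite calls were made for 99 genes in H1.2sh and Cul4Ash, 271 in H1.2sh and PAF1sh and 319 in Cul4Ash and PAF1sh. Independent lists would give 197, 368 and 494 such genes, and the simulated groups gave 23.6, 57.2 and 87.0. Their simulated correlation was 0.50, and the covariance of the log2 changes was 0.0267, 0.0261 and 0.0302 against 0.00475 simulated for each pair, a difference of 0.0220, 0.0214 and 0.0255. With 2 control arrays, the controls could not be split so that each part kept 2 arrays. With the 2 depletions of a pair set against different single control arrays, the mean covariance was 0.0206, 0.0200 and 0.0242. The mean Pearson correlation was then 0.2923, 0.2095 and 0.2298, below the values given above for shared controls. These covariances argue against chance values of single control arrays as the whole cause. Part of the excess of shared genes over independent lists may still come from such values, and part or all of it from a deviation common to both control arrays. The shared counts fell to 79 higher and 104 lower without NCsh replicate 1, 122 and 115 without NCsh replicate 2, 100 and 114 without H1.2sh replicate 1 and 106 and 120 without H1.2sh replicate 2, and they were 54 and 223 with median scaling. Without normalization 51 and 163 genes were shared, and with no filter on dim probes 103 and 110. On 5 arrays, neqc at an offset of 50 gave 64 and 93. At the planned offset it gave 0 and 0, since limma made no call there in H1.2sh or Cul4Ash.

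Set directly against Cul4Ash, H1.2sh was lower in the histone gene H2AC18 (-2.09 ± 0.09), TYMSOS (-1.99 ± 0.09) and CHCHD6 (-1.96 ± 0.11) and higher in DIAPH1 (2.52 ± 0.08), SLC6A9 (2.12 ± 0.08) and HMOX1 (1.85 ± 0.09). Of 27 core histone genes, 13 were lower in H1.2sh than in Cul4Ash and 0 higher (adjusted camera p = 3.99e-06, and adjusted p = 0.0854 with an estimated correlation). Of 37 genes of the ATF4 and amino acid response, 27 were higher and 1 lower (adjusted p = 2.26e-13, and 0.0854 with an estimated correlation). Of 70 oxidative phosphorylation genes, 21 were lower and 1 higher (adjusted p = 9.58e-07, and 0.108 with an estimated correlation). Adjusted over the list alone, the genes higher and lower were 1 and 15 for core histones, 27 and 2 for the ATF4 list and 1 and 25 for oxidative phosphorylation. In all, 1257 genes were higher and 1524 lower in H1.2sh, 2781 together. That count was 0 with neqc on 5 arrays (2695 at an unadjusted p under 0.05 in limma), 1552 without H1.2sh replicate 1, 1471 without H1.2sh replicate 2, 1574 without Cul4Ash replicate 1, 1661 without Cul4Ash replicate 2 and 1707 with median scaling. It was 1755 without normalization, 1820 with no filter on dim probes and 839 with neqc at an offset of 50 on 5 arrays.

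**Figure D4:**
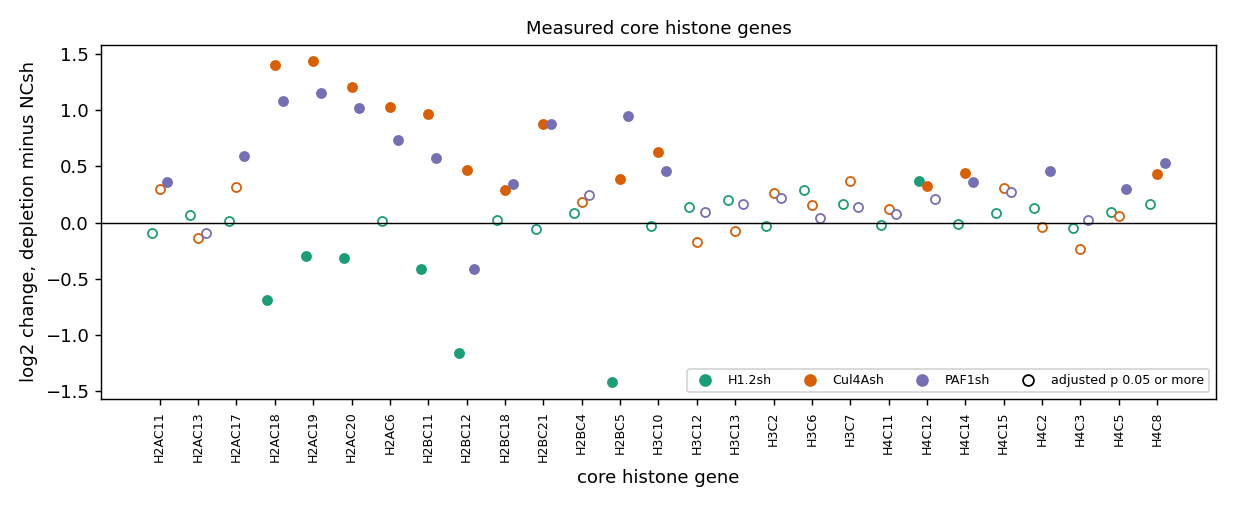
Log2 change against NCsh (vertical axis) of the 27 measured core histone genes (horizontal axis) in the 3 depletions, from means of 2 arrays per group; filled points have an adjusted p under 0.05. H2AC18 lies at -0.69 in H1.2sh, 1.40 in Cul4Ash and 1.08 in PAF1sh.

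Set against PAF1sh, H1.2sh was lower in TRIM51 (-3.51 ± 0.10), H2BC5 (-2.37 ± 0.09) and DHDH (at least 4.37-fold, not above background on the 1 H1.2sh array with an undisputed detection p-value) and higher in PAF1 (2.75 ± 0.08) and the D-type cyclin genes CCND2 (2.60 ± 0.08) and CCND1 (2.44 ± 0.08). Of 51 genes of G2 phase and mitosis, 37 were lower and 1 higher in H1.2sh (adjusted camera p = 8.67e-09, and adjusted p = 0.118 with an estimated correlation), and of 24 p53 target genes 15 were lower and 4 higher (adjusted p = 0.00285, and 0.118 with an estimated correlation). Of 27 core histone genes, 15 were lower and 0 higher (adjusted p = 5.13e-05, and 0.118 with an estimated correlation). Of 30 ribosome biogenesis genes, 13 were higher and 0 lower (adjusted p = 0.000859, and 0.118 with an estimated correlation). Adjusted over the list alone, the genes higher and lower were 1 and 38 for mitosis, 4 and 15 for p53 targets, 0 and 15 for core histones and 15 and 0 for ribosome biogenesis. The comparison gave 2427 genes higher and 2513 lower, 4940 together. That total was 957 with neqc on 5 arrays, 3104 with neqc at an offset of 50 and 3063 with the matrix values of those arrays.

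Cul4Ash was lower than PAF1sh in TRIM51 (at least 12.5-fold, not above background on the 1 Cul4Ash array with an undisputed detection p-value), DIAPH1 (-2.33 ± 0.08) and COL7A1 (-1.99 ± 0.09) and higher in PAF1 (2.58 ± 0.08), CTXN1 (2.27 ± 0.07) and CCND2 (2.26 ± 0.08). Of 25 HOX genes, 12 were higher and 3 lower in Cul4Ash (adjusted camera p = 0.00424, and adjusted p = 0.273 with an estimated correlation), and of 31 glycolysis and hypoxia genes 17 were higher and 3 lower (adjusted p = 0.00155, and 0.399 with an estimated correlation). Of 24 immediate early genes, 15 were lower and 2 higher, and of 37 genes of the ATF4 and amino acid response 23 were lower and 6 higher. Both of these lists had an adjusted p of 0.000840, and of 0.273 with an estimated correlation. Adjusted over the list alone, the genes higher and lower were 13 and 3 for HOX, 20 and 3 for glycolysis and hypoxia, 2 and 17 for immediate early and 6 and 23 for ATF4 genes. In all, 2607 genes were higher and 2438 lower in Cul4Ash, 5045 together. That total was 1232 with neqc on 5 arrays and 3266 with the matrix values of those arrays.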

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

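The tests of the column names, of S-phase genes and of the histone families were chosen after the result was seen. The S-phase test was first a single test and was split into 2 and extended to other scalings after its value was known, and the shared-gene counts under other scalings were known before the scaling test of the overlap. The count of shared genes still called under each scaling was chosen afterwards.

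Genes of the ATF4 and amino acid response differed between H1.2sh and Cul4Ash in the direct test, with a mean log2 difference of 0.48 (adjusted camera p = 2.26e-13, and adjusted p = 0.0854 with an estimated correlation). Probes without a gene name lie outside the gene comparisons: of 5826 kept, 4.26% differed from NCsh in H1.2sh, 9.39% in Cul4Ash and 17.7% in PAF1sh, against 10.6%, 15.5% and 33.1% of named probes.

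The scanner table and the matrix disagree on the names of 2 arrays. If the matrix were mislabelled, the targets named by the scanner columns would be low there, but they stood at 103.5% or more of the NCsh mean. The targets named by the matrix stood at 39.57% and 19.65%, consistent with names moved over by 1 array in the scanner table. No biological explanation was tested.

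The genes called alike in all 3 depletions may share a response to depletion or reflect the controls. Set against different control arrays, the lowest covariance of fold changes was 0.02003, which argues against chance values of single control arrays as the whole cause. A chromosome region in the control line holds too few of these genes to account for them, since the stretch of 52 neighbouring genes from LY6E to ZNF517 that stood above shuffled orders in the mean of the 3 depletions (permutation p = 0.018) held 0.5025% of them and 0.4234% of all genes placed, though such a region stays open for that stretch. The part of scaling cannot be told apart, because the 398 genes could not turn direction (100% kept it; the largest shift was 0.15 and their smallest change 0.22), and 224 were still called in all 3 with median scaling and 182 without normalization. A deviation common to both control arrays cannot be told apart from a shared response either, because it would move all 3 comparisons alike (56.78% of these genes differed in a direct comparison of depletions, and 56.34% of other genes), and an effect of hairpin expression was not tested.

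Core histone genes were higher in Cul4Ash and PAF1sh (adjusted p = 0.103 and 0.154 with an estimated correlation) and lower in H1.2sh than in Cul4Ash (adjusted camera p = 3.99e-06, and adjusted p = 0.0854 with an estimated correlation) and PAF1sh (5.13e-05, and 0.118). Genes in 4 histone families rose in Cul4Ash, so 1 cross-read transcript is not enough, and the lowest list mean in the 2 depletions under other scalings was 0.3846. A larger share of S-phase cells in Cul4Ash than in H1.2sh cannot be told apart from a change in histone transcripts. The mean difference of S-phase genes, H1.2sh minus Cul4Ash, was 0.0617 ± 0.0284 (SE over genes) with quantile normalization. It was 0.073 ± 0.0288 with median scaling and 0.01118 ± 0.0288 without normalization. The genes are not independent replicates, so this SE does not measure the spread between arrays. The list did not pass camera for this difference (adjusted p = 0.224, and 0.113 with median scaling). The sign of the means is opposite to a larger share in Cul4Ash, but the test does not decide it. Against NCsh the S-phase list passed as higher in H1.2sh (mean 0.158, adjusted p = 0.000125, and adjusted p = 0.173 with an estimated correlation), where core histones did not pass. A larger share than in NCsh cannot be told apart either, since the S-phase list did not pass in Cul4Ash or PAF1sh. Its mean in Cul4Ash was 0.0963, 0.012 with median scaling and 0.056 without normalization. In PAF1sh its mean was 0.022 and turned to -0.03875 and -0.032 under these scalings. A change in polyadenylated histone transcripts stays open as an untested hypothesis.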

How the results depend on the processing

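The tests with neqc at an offset of 16 cut to 5 arrays, with the matrix values of the same 5 arrays, with 50 added to the matrix values, with crossed numbers, with the scanner table's own column names and of the lists under other scalings were chosen after the data were seen. Counts are given per setting for H1.2sh, Cul4Ash and PAF1sh against NCsh (higher and lower), then for H1.2sh against Cul4Ash, H1.2sh against PAF1sh and Cul4Ash against PAF1sh, then for genes higher and lower in all 3 depletions. With the analysis of all 8 arrays reported above they were 895 and 1003, 1358 and 1180, and 2335 and 2447, then 2781, 4940 and 5045, then 196 and 202. The setting planned before the data were examined, neqc with an offset of 16 on scanner signals, could be run only on the 5 arrays with undisputed names and gave 0 and 0, 0 and 0, and 807 and 1210, then 0, 957 and 1232, then 0 and 0. Its counts of 0 from limma stood beside 2611 genes for H1.2sh, 3160 for Cul4Ash and 2695 between them at an unadjusted p under 0.05. With an offset of 50 neqc gave 327 and 414, 723 and 659, and 1736 and 1952, then 839, 3104 and 3367, then 64 and 93, and the matrix values of the same 5 arrays gave 340 and 398, 701 and 631, and 1653 and 1876, then 868, 3063 and 3266, then 66 and 79, so part of the loss came with the fewer arrays and the rest with neqc at the smaller offset. These fits have 1 array per depletion, which is assumed to vary like the control arrays. The limit to 5 arrays came from leaving out the 2 scanner arrays of disputed name, which match Cul4Ash replicate 2 and PAF1sh replicate 2 of the matrix. A neqc fit that takes their names from the matrix was not run. The array left out cannot alone account for the lack of calls in Cul4Ash, since the matrix values of the same arrays gave calls there. It may still have contributed. Scanner signals of these 5 arrays without background correction gave 763 and 833, 1185 and 1042, and 2064 and 2162, then 1589, 3732 and 4026, then 160 and 162, and a correlation of fold changes of 0.25 between H1.2sh and PAF1sh and 0.264 between Cul4Ash and PAF1sh; the cause was not tested.

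Median scaling of the matrix values gave 264 and 1198, 503 and 1279, and 1482 and 2248, then 1707, 3905 and 3960, then 54 and 223, and no normalization between arrays gave 201 and 1214, 571 and 794, and 1413 and 2069, then 1755, 3698 and 3677, then 51 and 163. No filter on dim probes gave 465 and 571, 866 and 715, and 1874 and 2052, then 1820, 4135 and 4211, then 103 and 110. A detection p under 0.01 on all 7 scanner arrays, in place of the planned 8, gave 296 genes higher in all 3 depletions, and a trend with a robust prior 310. A change of at least 1.5-fold gave 112 and 233, 216 and 259, and 524 and 745, then 527, 1341 and 1421, then 18 and 49, and an adjusted p under 0.01 gave 331 and 433, 638 and 514, and 1531 and 1675, then 1349, 3374 and 3469, then 74 and 80. Read with its own column names, the scanner table gave 0 and 0, 0 and 0, and 0 and 0, then 0, 0 and 0, then 0 and 0, with 769, 1403 and 1655 genes against NCsh and 255, 1362 and 151 in the direct comparisons at an unadjusted p under 0.05. Under that reading, 3 of the gene values that passed with all 8 arrays changed sign. By the match with the matrix, the group read as H1.2sh then held an array of Cul4Ash. CDKN1A went to 0.040 and HNRNPA1 to -0.045 in H1.2sh, for which the part of this mixing was not tested. CUL4A went to -0.15 in H1.2sh minus Cul4Ash, since it stood at 39.6% of the NCsh mean in the disputed column named for H1.2sh and at 116% in that named for Cul4Ash. Of 223 gene values followed, 95 stayed on their side of the threshold with neqc on 5 arrays and 128 no longer passed. Direction was checked only for values that passed in either fit. Since neqc made no call for H1.2sh or Cul4Ash against NCsh or between them, no value that passed in those comparisons kept its call. Array weights and fits of 4 arrays moved no count by over 1.5 times.

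Leaving out each array in turn gave 306 to 880 genes higher and 446 to 978 lower in H1.2sh, 690 to 1336 and 599 to 1159 in Cul4Ash, 1798 to 2313 and 1904 to 2432 in PAF1sh, and 79 to 186 and 104 to 176 in all 3. The direct comparisons gave 1471 to 2737, 3700 to 4871 and 3900 to 5003, the correlations of fold changes 0.371 to 0.492, 0.274 to 0.339 and 0.28 to 0.354, and the lists that passed 11 to 14, 4 to 5 and 7 to 9. With an estimated correlation, 0, 0 and 0 lists passed camera, with 7, 5 and 5 at an unadjusted p under 0.05, and 20, 13 and 26 passed fry, which does not compare a list with other genes. Median scaling and no normalization differ only by a constant per array, which camera hardly sees, so passing under both is nearly the same test. With these other scalings, 23 of 26 list shifts passed. The PAF1 complex, Polycomb and matrix lists in H1.2sh did not. Under both, 5 more lists passed: NRF2 (adjusted p = 0.0152), HOX (0.0321) and cytosolic ribosomal protein genes (0.0235, with a mean of 0.035 that turned to -0.0035 without normalization) in H1.2sh, TGF-beta targets in Cul4Ash (0.0324) and p53 targets in PAF1sh (0.00890).

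Replicate numbers are shared by the groups, but the deviations of same-numbered arrays correlated between -0.133 and 0.111, so the numbers were not taken as pairs. With the replicate number as a block the counts were 775 and 909, 1246 and 1070, and 2267 and 2377, then 2487, 4760 and 4881, then 177 and 172. With the numbers of the H1.2sh arrays crossed they were 885 and 1038, 1377 and 1202, and 2413 and 2493, then 2817, 4981 and 5099, then 193 and 197. A block for the BeadChip was not run, since the files name no chip. Arrays detected between 39.2% and 42.5% of probes above background, which limits what can be said of dim genes.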

Other observations

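The test of small RNA genes, and the values of the stretch from LY6E to ZNF517 in each depletion, were chosen after the result was seen.

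Genes that neighbour each other moved together in H1.2sh. Along 59 genes from RBM26 to CHAMP1, 50 had a change under 0, with a median log2 change of -0.26. Other stretches ran from PACC1 to LBR (44 genes, median -0.19), from UCHL5 to ADORA1 (37 genes, -0.19), from SCRIB to ZNF251 (33 genes, 0.22), from NACA to MON2 (37 genes, 0.19) and from FBXO31 to MC1R (35 genes, 0.18). The hypothesis tested was that a chromosome region was gained or lost in a depleted line. The largest median over 31 neighbouring genes was -0.3186 in H1.2sh, against a size of at most 0.238 in shuffled gene orders (permutation p = 0.001, the smallest these shuffles can give), while Cul4Ash (p = 0.196) and PAF1sh (p = 0.146) did not stand apart. In the mean of the 3 depletions, 52 genes from LY6E to ZNF517 had a median of 0.18, with 41 above 0 (largest run median 0.19 against 0.18 for 95% of shuffled orders, permutation p = 0.018), and their medians were 0.17 in H1.2sh, 0.14 in Cul4Ash and 0.19 in PAF1sh. All 33 genes from SCRIB to ZNF251 lie in that stretch, so a region lost in the control line stays open for it. Copy number may account for the other stretches, but an effect of H1.2 depletion on whole regions or of base composition was not tested.

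Some small non-coding RNA genes, singled out after their values were seen, were higher in PAF1sh, such as SNORD3A (1.44), SNAR-A1 (1.23) and RN7SK (0.98). The hypothesis that small RNA genes as a class were called higher more often than other genes in PAF1sh was not borne out: 40 of 214 were, 18.69% against 18.99% of other genes (Fisher's exact test, two-sided, p = 1).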
